A study of Mus musculus with 4 samples.

How the data were processed

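RNA was sequenced from c-Kit high leukemic cells of 2 Msi2 -/- and 2 Msi2 flox/flox mice, 1 library per mouse. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy kit, libraries were made with the Illumina TruSeq RNA kit and selected for fragment length, and both ends were read on a HiSeq 2000. Trimmomatic, STAR, HTSeq and DESeq and the mouse build mm9 are named in the submitters' processing notes, without versions. The annotation, the strand setting and the overlap mode of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. The deposited values are raw read counts per gene symbol, whole numbers that the authors did not normalize, for 23284 gene rows and 5 closing rows that name no gene. The closing rows took 19.1%, 20.1%, 19.5% and 19.3% of the counts in control 1, control 2 and Msi2 -/- replicates 1 and 2, and were left out of library sizes and tests. Gene counts totalled 79845492, 72273679, 87564774 and 78659396 in the same order, and 3 counts correspond to between 0.0343 and 0.0415 CPM.

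Groups were taken from the sample titles and genotype labels. The design text places each library in a separate mouse. The library names begin with a number shared within a group and different between groups, whose meaning is not given in the sources used here; if it marks a batch, batch and group cannot be told apart. Before averaging, the replicates were compared: the chi-square statistic per gene was 59.2 between the controls and 144 between the Msi2 -/- libraries, far above sampling noise, so each library counts as 1 sample.

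In R 4.3.3, edgeR 4.0.16 was the main test. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15, by group), library sizes were scaled by TMM, and a quasi-likelihood model with group as the only term was tested on both sides, with Benjamini-Hochberg adjusted p under 0.05 over 13215 genes. Fold changes are log2, Msi2 -/- minus control. The standard error of a fold change was taken from its quasi-likelihood F statistic. CPM are relative to the TMM-scaled library sizes and are given as mean ± SD of 2 mice. DESeq2 1.42.0 (Wald test, no shrinkage of fold changes) gave an adjusted p for 13350 genes and is reported beside edgeR. The prior of edgeR's quasi-likelihood spread had 2.29 degrees of freedom.

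In all, 29 gene lists were fixed before the data were examined, and the 28 that are not sex-linked were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. An estimated correlation and fry, which tests whether the genes of a list move on balance 1 way or, in its mixed form, in either direction, were alternatives. With an estimated correlation camera rests on the few residual degrees of freedom of 4 libraries, so lists could hardly pass whatever their correlation. Where a library was left out, 1 group held a single mouse. Camera's p then measures how that mouse differs from the other group, and cannot separate this from genotype. Adjustment over a list alone used edgeR's p-values of its members. The rule for named genes, also fixed beforehand, took Msi2, then Hoxa9, Hoxa10, Meis1, Myc, Ikzf2, Myb, Kit, Cd34 and Itgam whatever their result, then up to 10 genes per direction past 0.05 with a mean log2 CPM of at least 3, without overlap of the groups and with an established symbol. It further took up to 4 members of smallest p past 0.05, or else the 2 of smallest p, in each primary or called list. It named 28 genes. Hoxa9, Myc and Ikzf2 are known to be part of this study's subject, so their choice is not independent of it. The largest changes by DESeq2 and a few further genes were added after the data were examined. Genes of X and Y, and neighbours of Msi2, were found by symbol in the RefSeq gene table of the assembly GRCm38.p6, where 98.9% of the gene rows matched. Its coordinates are not used here, as the files are on another build. Single-gene results for some genes of the lists are not reported here.

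The edgeR and DESeq2 steps were tested on simulated counts for 13215 genes of this comparison, with 200 genes changed. A small further set was raised by less than 2-fold. At 2-, 4- and 8-fold edgeR recovered 57.4%, 84.8% and 95.5% of the changed genes with 25 false calls in all. DESeq2 recovered 70.6%, 95.5% and 97% with 85 false calls. For both tools, and more so for DESeq2, false calls were a larger share than the threshold of 0.05. The draws used only edgeR's gene-wise estimates of spread. With the real counts edgeR did not call Msi2 at a log2 fold change of -8.07 (adjusted p = 0.122). The recovered shares therefore do not give the power of the real comparison. The alternatives tried were RLE and upper-quartile scaling, no filter and a filter at 1 CPM in 2 libraries, DESeq2, limma-voom, edgeR's likelihood ratio test, glmTreat against 1.5-fold, an adjusted p of 0.1, thinning to the smallest library, the replicate number as a block, leaving out each library, and leaving out genes of X and Y.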

Results

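The study asked what loss of Msi2, a gene for an RNA-binding protein of the Musashi family, does to the transcripts of leukemic stem-like cells driven by MLL. RNA was sequenced from leukemic cells sorted for high c-Kit, a receptor found on immature blood cells. Cells came from 2 mice lacking Msi2 (Msi2 -/-) and 2 mice with loxP-flanked, intact alleles (Msi2 flox/flox, called control here). Each of the 4 libraries is 1 mouse. Reads assigned to genes numbered 79845492 and 72273679 in control 1 and control 2, and 87564774 and 78659396 in Msi2 -/- replicates 1 and 2. At this depth 3 counts correspond to between 0.0343 and 0.0415 CPM, the unit in which gene counts are scaled by library size. Of 23284 gene rows, 13215 had enough counts to be tested.

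Msi2 transcripts were close to the floor in both Msi2 -/- libraries. The gene had 2804 and 3562 counts in the controls and 8 and 17 counts in the Msi2 -/- mice, or 41.7 ± 10.1 CPM against 0.156 ± 0.0915 CPM (SD, n = 2 each). Its log2 fold change was -8.07 (SE 0.485), with an adjusted p of 0.122 by edgeR's quasi-likelihood test and 6.35e-80 by DESeq2. The counts cover the whole gene, and which exons were deleted is not given in the sources used here. Msi1, the other Musashi gene, stood at 0.395 and 0.851 CPM in the controls and at 1.85 and 1.55 CPM in the Msi2 -/- libraries (log2 fold change 1.45, SE 0.496, edgeR adjusted p = 0.372). It was chosen after its values were seen.

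Ikzf2, which encodes Helios, a zinc finger transcription factor of the Ikaros family, fell with the loss of Msi2. It went from 86.9 ± 10.1 CPM in the controls to 0.856 ± 0.0944 CPM in the Msi2 -/- mice (SD, n = 2 each), a log2 fold change of -6.67 (SE 0.172). Both Msi2 -/- libraries lay below both controls, with 69 and 71 counts against 6465 and 6855. Ikzf2 was the only gene past an adjusted p of 0.05 by edgeR (adjusted p = 0.0165), so edgeR called 0 genes higher and 1 lower. The next smallest adjusted p by edgeR was 0.0872, for Acot7, an acyl-CoA thioesterase gene with a log2 fold change of -2.42 (SE 0.108). At an unadjusted p under 0.05, edgeR had 884 genes higher and 815 lower. At an adjusted p under 0.05, DESeq2 called 414 higher and 362 lower, and limma-voom called 0 in each direction. At that adjusted threshold edgeR's likelihood ratio test called 120 higher and 192 lower. With control 1 or control 2 left out, edgeR's quasi-likelihood test called 0 genes and Ikzf2 had an adjusted p of 0.255 in each case, at log2 fold changes of -6.78 and -6.54. Without Msi2 -/- replicate 1 or 2 the log2 fold change of Ikzf2 was -6.55 and -6.78. More genes were then called, but spread was taken from the 2 controls alone.

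**Figure D1:**
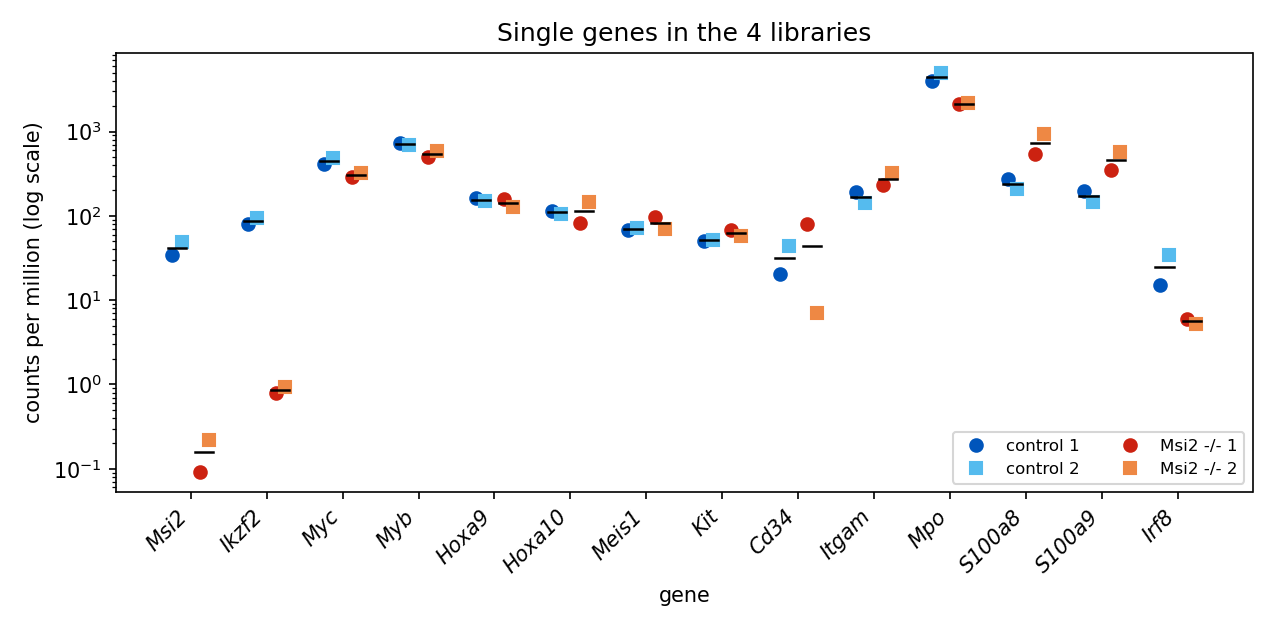
CPM, on a log axis, of 14 genes in the 4 libraries; each point is 1 mouse and each bar the mean of the 2 mice of a group. Of the 14 genes, Msi2 and Ikzf2 show the widest gaps between groups (86.9 against 0.856 CPM for Ikzf2), Mpo, Myc and Myb lie lower in both Msi2 -/- mice, and Cd34 differs more between the 2 Msi2 -/- mice (79.8 and 7.02 CPM) than between groups.

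Among DESeq2's calls with a mean log2 CPM of at least 3, an established symbol and no overlap of the groups, the 10 highest log2 fold changes were those of Epha2, Cd48, Tgm2, Ckm, S100a6, Tanc1, Ltf, Amot, Lcn2 and Hsd11b1. Epha2, an ephrin receptor gene, went from 2.21 ± 1.06 to 14.0 ± 1.56 CPM (log2 fold change 2.66, SE 0.409, DESeq2 adjusted p = 3.22e-08). Cd48, which encodes a surface protein low on long-term stem cells, went from 3.53 ± 2.64 to 18.8 ± 9.44 CPM (log2 fold change 2.42, SE 0.715, DESeq2 adjusted p = 0.00505). With a library left out, edgeR's log2 fold change was 3.25 for Epha2 without control 1, and for Cd48 it ran from 1.79 without Msi2 -/- replicate 2 to 3.50 without control 2. The 10 lowest were those of Xist, Msi2, Ikzf2, Zfp783, Tfpi, Vill, Hebp2, Serpinf1, Grb14 and Fnbp1l. Tfpi, which encodes an inhibitor of the tissue factor clotting pathway, went from 23.4 ± 5.73 to 1.64 ± 0.199 CPM (log2 fold change -3.83, SE 0.266, DESeq2 adjusted p = 2.61e-37). Zfp783 had 0.172 and 0.195 CPM in the Msi2 -/- mice, but its controls differed at 29.0 and 7.22 CPM. The ranking rested in part on single libraries. Tanc1, Amot, Ikzf2, Tfpi and Grb14 moved by less than 1.5-fold whichever library was left out, and the others by more. Without Msi2 -/- replicate 1 the log2 fold change was 0.75 for Ckm, against 2.12 with all libraries. Without replicate 2 it was 1.08 for S100a6, 1.15 for Hsd11b1, 1.60 for Tgm2, -5.50 for Hebp2, -4.00 for Serpinf1 and -3.40 for Fnbp1l, against 2.01, 1.78, 2.22, -3.57, -3.16 and -2.77. Without control 1 it was -5.29 for Zfp783 and -1.69 for Vill, against -6.62 and -3.66. These genes were picked from DESeq2's calls after the data were examined, and none of them except Ikzf2 passed edgeR's test. In the simulated counts, the share of DESeq2's calls that were false exceeded its threshold of 0.05, so its adjusted p-values may be too small. Of DESeq2's 776 calls, 772 were also tested by edgeR and showed no overlap of the groups, which a call at 2 against 2 nearly implies. Of all tested genes 48.3% showed none, where chance gives 33.3% for 2 against 2. DESeq2 called 220 higher and 170 lower without control 1, 102 higher and 95 lower without control 2, and 600 lower without Msi2 -/- replicate 2. Of the 776 genes, 251 were still called without control 1 and 150 without control 2.

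Xist, the transcript that silences the inactive X chromosome in female cells, separated the groups too. It had 1455 and 654 CPM in control 1 and control 2 and 0.469 and 0.624 CPM in the Msi2 -/- mice (edgeR adjusted p = 0.122, DESeq2 adjusted p = 6.04e-80). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 41.1 CPM in control 1, 184 CPM in control 2, and 225 and 242 CPM in Msi2 -/- replicates 1 and 2. Control 1 thus held 17.6% and control 2 held 79.1% of the mean Y-linked level of the Msi2 -/- libraries, together with Xist. The labels give no sex. With the 420 tested genes of X and Y left out, DESeq2 called 756 genes.

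The HOXA and MEIS1 program, the transcription factors that MLL fusion proteins keep active, did not pass the list test. Hoxa9 stood at 156 ± 9.44 CPM in the controls and 144 ± 23.6 CPM in the Msi2 -/- mice (log2 fold change -0.11, SE 0.136). Hoxa10 had a log2 fold change of 0.04 (SE 0.292) and Meis1 of 0.25 (SE 0.179), and the groups overlapped for all 3 genes. Of 26 tested members, 0 passed by edgeR over all genes, 1 was lower when adjusted over the list alone, and DESeq2 called 0 higher and 2 lower (edgeR at unadjusted p under 0.05: 1 higher, 4 lower). The 2 members of smallest p were Six4, a homeobox gene (39.0 ± 1.39 to 21.6 ± 2.33 CPM, log2 fold change -0.85, SE 0.124, DESeq2 adjusted p = 1.95e-06), and Igf2bp2, an RNA-binding protein gene (4.40 ± 0.855 to 1.53 ± 0.439 CPM, log2 fold change -1.52, SE 0.349, DESeq2 adjusted p = 0.00943). The median log2 fold change was 0.04, the mean -0.13 and camera's direction down (adjusted p = 0.658). Without Msi2 -/- replicate 2 the list lay lower with an adjusted p of 0.00414.

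Regulators of blood and leukemia stem cells included the single edgeR call, Ikzf2. The list had 31 tested members, of which edgeR called 0 higher and 1 lower over all genes tested. Adjusted over the list alone, 1 was higher and 4 lower, and DESeq2 called 3 higher and 5 lower. Myb, a transcription factor gene of blood progenitors, stood at 715 ± 35.4 CPM in the controls and 546 ± 64.6 CPM in the Msi2 -/- mice (log2 fold change -0.39, SE 0.109, edgeR adjusted p = 0.335, DESeq2 adjusted p = 0.0417). Kit, whose protein was used for the sort, had 51.1 ± 1.04 and 62.6 ± 7.77 CPM (log2 fold change 0.29, SE 0.111, edgeR adjusted p = 0.396). Cd34, a progenitor surface marker, had 20.3 and 43.5 CPM in the controls and 79.8 and 7.02 CPM in the Msi2 -/- mice. Camera placed the list lower without passing the threshold (adjusted p = 0.187, median log2 fold change -0.15). It passed at 0.0367 without Msi2 -/- replicate 1.

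Targets of MYC, the transcription factor that drives ribosome production and growth, lay slightly lower in the Msi2 -/- cells. Of 60 tested members 44 had a log2 fold change below 0 and 16 above, with a median of -0.09 and a camera adjusted p of 0.0443. The call was lost with adjusted p = 0.975 with an estimated correlation, which was 0.53 between genes of this list. By edgeR 0 members passed over all genes tested and 0 adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 0. The 2 members of smallest p were Supv3l1, a mitochondrial RNA helicase gene (log2 fold change -0.26, SE 0.076), and Shmt1, a serine metabolism enzyme gene (log2 fold change -0.20, SE 0.07). Myc itself stood at 448 ± 58.4 CPM in the controls and 304 ± 25.9 CPM in the Msi2 -/- mice (log2 fold change -0.56, SE 0.125, edgeR adjusted p = 0.308, DESeq2 adjusted p = 0.00399). The list's median against the control mean was -0.02 in Msi2 -/- replicate 1 and -0.20 in replicate 2. The camera adjusted p was 0.126 without control 1, 0.0669 without control 2, 0.0559 with no filter on low counts, 1.82e-05 without Msi2 -/- replicate 1, and 0.627 in the upward direction without replicate 2.

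Late neutrophil genes stood higher in the Msi2 -/- cells. Of 28 tested members 22 had a log2 fold change above 0 and 6 below, with a median of 0.78. S100a8 and S100a9, which encode the subunits of calprotectin, went from 242 ± 44.7 to 737 ± 284 CPM and from 171 ± 35.2 to 457 ± 153 CPM (log2 fold changes 1.61, SE 0.316, and 1.42, SE 0.29; DESeq2 adjusted p = 3.42e-06 and 1.83e-05). Ltf, for lactoferrin, and Lcn2, for lipocalin 2, both secondary granule proteins, had log2 fold changes of 1.87 (SE 0.459) and 1.78 (SE 0.498). Both were picked from DESeq2's largest changes. For the neutrophil granule genes Ngp and Camp the groups overlapped. Their log2 fold changes were 0.38 (SE 0.327, DESeq2 adjusted p = 0.613) and 0.67 (SE 0.704, DESeq2 adjusted p = 0.835). The 2 Msi2 -/- mice were unequal, at 21.3 and 9.16 CPM for Ltf and 38.0 and 96.7 CPM for Lcn2, and the log2 fold change was 1.15 for Ltf without replicate 1 and 0.96 for Lcn2 without replicate 2. Cxcr2, a chemokine receptor gene of mature neutrophils, went the other way at -1.63 (SE 0.487, DESeq2 adjusted p = 0.0319). The list's camera adjusted p was 0.000924, and adjusted p = 0.926 with an estimated correlation. By edgeR 0 members passed over all genes tested and 0 adjusted over the list alone (7 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 4 higher and 1 lower.

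Mpo, the myeloperoxidase gene of primary granules, stood at 4477 ± 673 CPM in the controls and 2138 ± 30.2 CPM in the Msi2 -/- mice (log2 fold change -1.07, SE 0.127, edgeR adjusted p = 0.265, DESeq2 adjusted p = 8.4e-12). Mpo is a neighbour of Msi2, with 7 tested genes between them in the GRCm38.p6 RefSeq table. Elane, for neutrophil elastase, had 4426 ± 308 and 5428 ± 1700 CPM, and Ms4a3 had 869 ± 119 and 1319 ± 517 CPM. Of 15 tested members 9 lay above 0 and 6 below; edgeR called 0 over all genes and 1 lower adjusted over the list alone (0 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 1 lower. The median was 0.05, the mean -0.02, camera's direction up (adjusted p = 0.946) and fry's down. The medians of the 2 Msi2 -/- libraries were on opposite sides of the controls, at -0.23 in replicate 1 and 0.40 in replicate 2. Camera gave an adjusted p of 0.000281 upward without replicate 1 and 0.00115 downward without replicate 2.

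Monocyte and macrophage genes split in the same manner, with a median against the controls of -0.64 in Msi2 -/- replicate 1 and 0.44 in replicate 2. Itgam, the integrin gene for CD11b, had 168 ± 34.5 CPM in the controls and 276 ± 62.5 CPM in the Msi2 -/- mice (log2 fold change 0.72, SE 0.224, edgeR adjusted p = 0.357, DESeq2 adjusted p = 0.0319). Irf8, a transcription factor gene of monocytes and dendritic cells, had 25.0 ± 13.7 and 5.64 ± 0.542 CPM (log2 fold change -2.15, SE 0.442, DESeq2 adjusted p = 5.76e-05, and log2 fold change -1.44 without control 2). Cd300ld, a myeloid receptor gene, had 2.10 ± 0.118 and 6.32 ± 1.22 CPM (log2 fold change 1.59, SE 0.263, DESeq2 adjusted p = 3.96e-05). Of 35 tested members edgeR called 0 over all genes tested and 0 adjusted over the list alone (4 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 3 higher and 1 lower. Camera's adjusted p was 0.66 with both libraries, and its direction was up without Msi2 -/- replicate 1 and down without replicate 2. The estimated correlation of the list was 0.292.

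**Figure D2:**
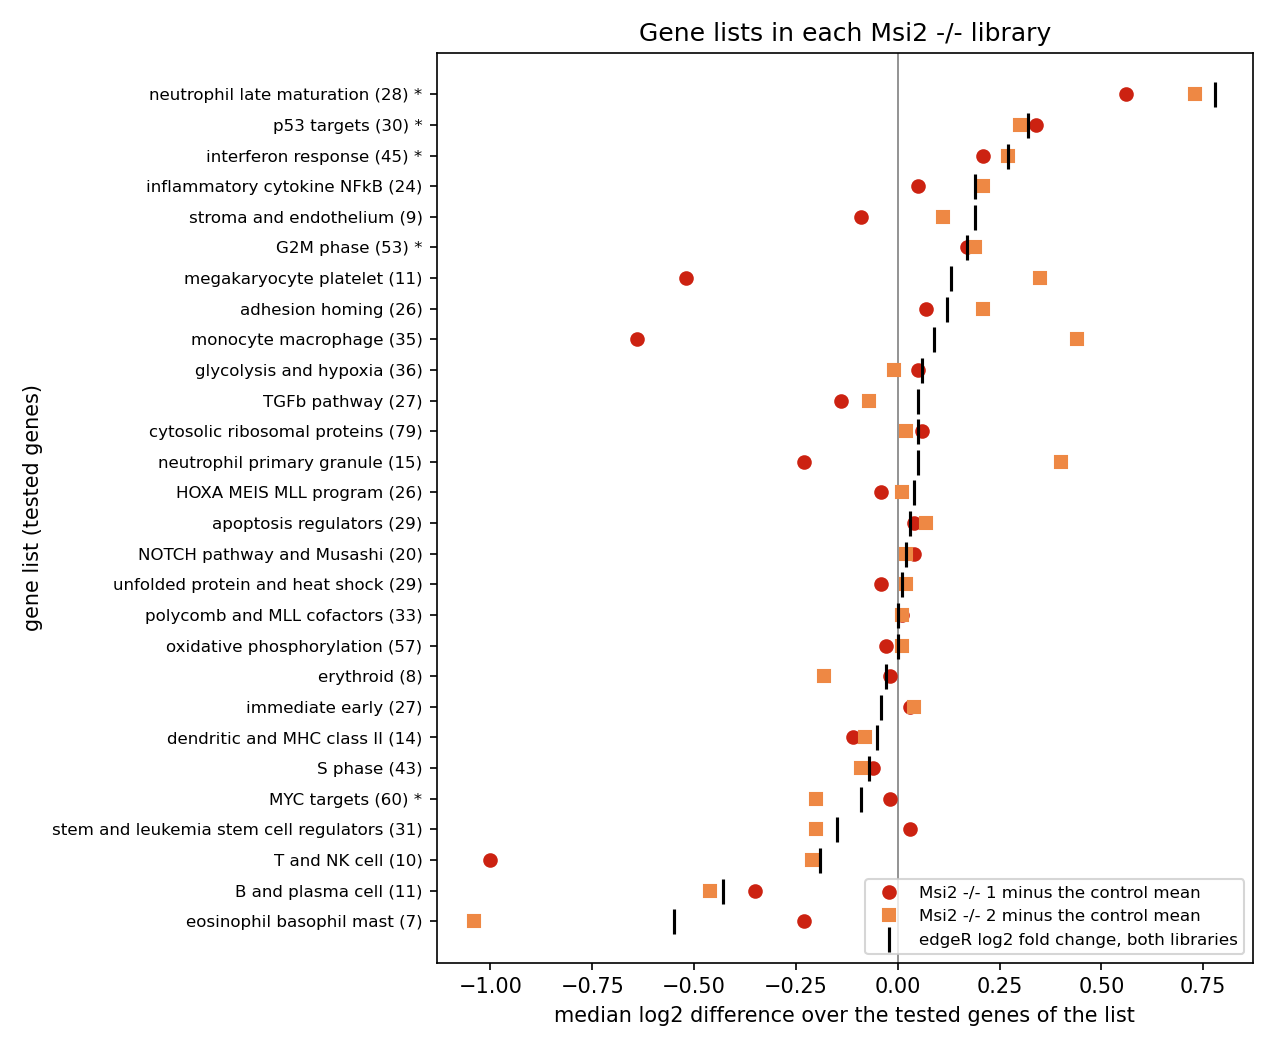
Median log2 difference over the tested genes of each of 28 gene lists, with the number of tested genes in brackets; circles and squares are Msi2 -/- replicates 1 and 2, each minus the control mean, and ticks are edgeR's log2 fold change over both. Asterisks mark the 5 lists past a camera adjusted p of 0.05 with the preset correlation; the monocyte and macrophage list lies at -0.64 in replicate 1 and 0.44 in replicate 2.

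Genes of the G2 and M phases stood slightly higher in the Msi2 -/- cells, and the S phase list did not pass its test. Of 53 tested G2 and M genes 47 had a log2 fold change above 0 and 6 below, with a median of 0.17. Nusap1, a spindle protein gene, went from 69.8 ± 6.2 to 106 ± 0.315 CPM and Mki67, the proliferation marker, from 841 ± 21.7 to 1121 ± 81.2 CPM (log2 fold changes 0.60, SE 0.086, and 0.42, SE 0.083). The camera adjusted p was 8.44e-07, and adjusted p = 0.963 with an estimated correlation. By edgeR 0 members passed over all genes tested and 0 adjusted over the list alone (13 higher and 0 lower at an unadjusted p under 0.05), and DESeq2 called 7 higher and 0 lower. Of 43 S phase genes 28 lay below 0, with a median of -0.07 and a camera adjusted p of 0.238. E2f8, a transcription factor gene, had a log2 fold change of 0.36 (SE 0.064) and Cdc45, a replication helicase gene, of -0.41 (SE 0.101). By edgeR 0 S phase genes passed over all genes tested and 0 adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05), and DESeq2 called 1 each way. Camera's direction for the S phase list was down without control 1 and up without control 2, and the list's estimated correlation was 0.562.

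Targets of the tumor suppressor p53 stood higher in both Msi2 -/- mice. Of 30 tested members 24 had a log2 fold change above 0, the median being 0.32, at 0.34 in replicate 1 and 0.30 in replicate 2. Zmat3, an RNA-binding protein gene, went from 84.2 ± 6.45 to 145 ± 3.22 CPM and Ccng1, for cyclin G1, from 275 ± 20.3 to 454 ± 18.4 CPM (log2 fold changes 0.78, SE 0.083, and 0.72, SE 0.085; DESeq2 adjusted p = 6.79e-11 and 3.61e-10). Cdkn1a, the cell cycle inhibitor p21, had 196 ± 67.3 and 384 ± 27.7 CPM (log2 fold change 0.97, SE 0.257). Cdkn2a encodes p16 and p19, of which p19 acts upstream of p53 rather than as its target. Cdkn2a had 13.8 ± 5.38 and 33.2 ± 0.693 CPM (log2 fold change 1.27, SE 0.301). Mdm2 and Bax were at 0.32 (SE 0.109) and 0.38 (SE 0.126). By edgeR 0 members passed over all genes tested, 7 were higher and 0 lower adjusted over the list alone (12 higher and 2 lower at an unadjusted p under 0.05), and DESeq2 called 10 higher and 1 lower. The camera adjusted p was 2.1e-06, and adjusted p = 0.926 with an estimated correlation.

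Interferon response genes stood higher by a smaller amount. Of 45 tested members 34 had a log2 fold change above 0, with a median of 0.27. Bst2, for tetherin, went from 54.9 ± 1.06 to 74.7 ± 0.928 CPM and Stat2, a signal transducer gene, from 50.7 ± 1.47 to 68.1 ± 2.76 CPM (log2 fold changes 0.44, SE 0.067, and 0.42, SE 0.076). By edgeR 0 members passed over all genes tested and 0 adjusted over the list alone (5 higher and 0 lower at an unadjusted p under 0.05), and DESeq2 called 5 higher and 0 lower. The camera adjusted p was 0.0048, and adjusted p = 0.926 with an estimated correlation. It was 0.261 without Msi2 -/- replicate 2. Of the 28 lists tested, 5 passed by camera with its preset correlation and 0 with an estimated correlation. Late neutrophil genes had an estimated correlation of -0.007, below the preset 0.01, so correlation did not undo that call. The estimate was above the preset for G2 and M genes (0.311), p53 targets (0.215) and interferon genes (0.029), as for MYC targets. The p-values of these lists at the preset correlation may thus be too small. Fry's directional form, which asks whether a list's genes move on balance 1 way without comparing them with other genes, passed 0 lists. The p-values of its mixed form were not adjusted over lists. The smallest were 0.000222 for apoptosis regulators and 0.000652 for stem cell regulators. For the lists called by camera, fry's mixed p was 0.00261 (interferon), 0.0396 (p53), 0.0526 (late neutrophil), 0.0762 (G2 and M) and 0.365 (MYC). With the preset correlation 8 lists had an unadjusted camera p under 0.05.

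Lists of markers of other blood and stromal cells passed no camera test. The median log2 fold change and camera adjusted p were -0.05 and 0.946 for dendritic and MHC class II genes, -0.55 and 0.14 for eosinophil, basophil and mast cell genes, and -0.03 and 0.946 for erythroid genes. They were 0.13 and 0.7 for megakaryocyte and platelet genes, -0.19 and 0.305 for T and NK cell genes, -0.43 and 0.17 for B and plasma cell genes, and 0.19 and 0.953 for stromal and endothelial genes. The T cell receptor genes Cd3d, Cd3e and Cd3g together had 3, 4, 16 and 2 counts in control 1, control 2 and Msi2 -/- replicates 1 and 2. The eosinophil, basophil and mast cell list passed downward with no filter on low counts (adjusted p = 0.00587), without control 2 (0.00268) or without Msi2 -/- replicate 1 (0.0016), and the B cell list without Msi2 -/- replicate 1 (0.0403).

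Housekeeping, signalling and stress lists passed no camera test. Cytosolic ribosomal protein genes had a median log2 fold change of 0.05 (79 genes, adjusted p = 0.14) and oxidative phosphorylation genes of 0 (57 genes, 0.953). Glycolysis and hypoxia genes had a median of 0.06 (0.946), heat shock and unfolded protein genes 0.01 (0.946), apoptosis regulators 0.03 (0.7), and polycomb and MLL cofactors 0 (0.953). The median was 0.05 for the TGF-beta pathway (0.922), 0.02 for Notch and Musashi genes (0.873), -0.04 for immediate early genes (0.946), 0.19 for inflammatory cytokine genes (0.238) and 0.12 for adhesion and homing genes (0.238). For adhesion and homing genes camera's direction was up without Msi2 -/- replicate 1 and down without replicate 2, and the estimated correlation was 0.135. Median and mean had opposite signs in 9 lists: the HOXA program, primary granule, megakaryocyte, stromal, apoptosis, TGF-beta, heat shock, inflammatory and adhesion lists. Camera's direction was up against a negative median and mean for the dendritic and the immediate early lists.

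The 2 Msi2 -/- mice differed from each other by more than the 2 controls did. Of 9223 genes with a mean log2 CPM of at least 3, 48 were at least 8-fold apart between the Msi2 -/- libraries and 3 (Hnf4a, Ly6k and Stag3) between the controls. The first principal component held 53.8% of the variance and separated the groups, and the second, with 32%, separated the 2 Msi2 -/- mice. In Msi2 -/- replicate 1, 38 of the 48 genes were lower, and 33 of these were over 8 CPM in both controls. Hoxa11, a homeobox gene, had 24.7 and 17.6 CPM in the controls, 0.4 CPM in replicate 1 and 57.5 CPM in replicate 2. Eya1, a cofactor gene of homeobox proteins, had 81.4 and 73.7 CPM in the controls and 0.652 and 27.8 CPM in the Msi2 -/- mice. Mecom, for the stem cell factor EVI1, had 8.78 and 9.73 against 0.0343 and 13.1 CPM. Its mean log2 CPM of 2.99 left it just outside the 9223 genes, so it is not 1 of the 48. Ccr2, a monocyte chemokine receptor gene, had 130 and 199 against 19.98 and 312 CPM. Stfa1, for stefin A1, had 97.3 and 27.4 against 1355 and 161 CPM. These genes were chosen after their values were seen, and none of them passed edgeR's test.

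**Figure D3:**
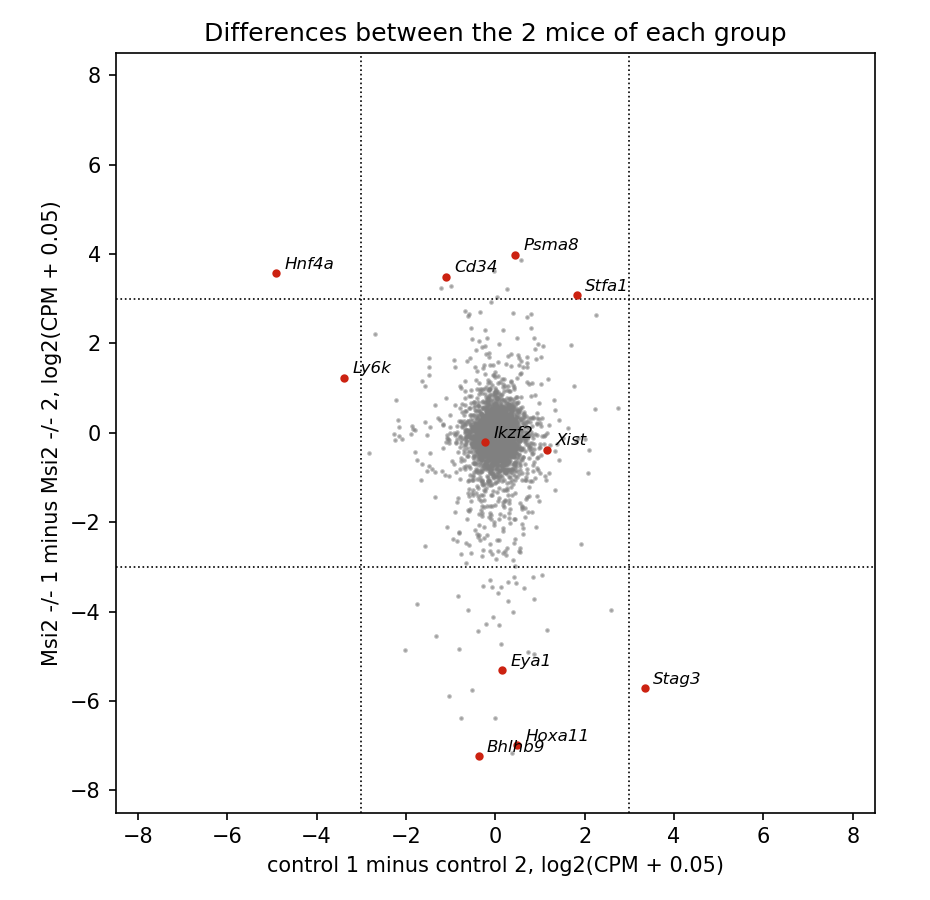
Difference between the 2 controls (x axis) and between the 2 Msi2 -/- mice (y axis), each as log2(CPM + 0.05), for 9225 genes with a mean log2 CPM, rounded to 2 decimals, of at least 3; dotted lines mark 8-fold, and the genes named in red were chosen for their position. More genes lie beyond 8-fold along the y axis (48 at the prior count of the tests) than along the x axis (3).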

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

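The likelihood ratio test, the settings without X and Y genes and every DESeq2 fit with a library left out or a block were chosen after the data were examined; the other settings were planned. Each group holds 2 mice, and where a library is left out the lone one is assumed to vary like the other group. Over all settings, 401 single-gene results kept their direction and side of the threshold, 52 passed it only under the alternative, 3 no longer passed it and 8 turned; for gene lists these numbers were 222, 11, 15 and 31. The causes of the changes were not tested. Leaving out a library leaves fewer samples, which alone would not raise edgeR's calls, as happened without either Msi2 -/- library. Spread in those fits came from the 2 controls alone. Their chi-square per gene was 59.2, against 144 between the Msi2 -/- libraries. Scaling moved the median of all genes by 0.003 (RLE) and -0.023 (upper quartile) on the log2 scale. Neither changed a gene call, and RLE, the one run on gene lists, changed no list call. Depth, at 72273679 or more gene counts per library, limits mainly genes near 3 counts, and thinning to the smallest library changed no count of edgeR calls by over 1.5 times. The replicate numbers do not pair the mice: deviations of same-numbered libraries correlated at 0.039 over genes. With the replicate number as a block, edgeR called 0 genes lower (Ikzf2 adjusted p = 0.0602, log2 fold change -6.66), DESeq2 called 223 higher and 239 lower, the MYC target list had an adjusted p of 0.0604, and no other edgeR gene call or list call changed.

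By number of genes, edgeR's 0 higher became 414 with DESeq2 and 120 with the likelihood ratio test, and stayed 0 with limma-voom. Its 1 lower became 362 with DESeq2, 192 with the likelihood ratio test, 6 with no filter on low counts, 2 at an adjusted p of 0.1 and 0 with limma-voom. Leaving out 1 library gave 0 to 23 higher and 0 to 83 lower by edgeR, and 102 to 299 higher and 95 to 600 lower by DESeq2. The Msi2 log2 fold change passed at -8.066 with no filter, -8.081 with DESeq2 and -8.067 with the likelihood ratio test, and ran from -8.81 to -7.54 with a library left out, passing without Msi2 -/- replicate 1 (adjusted p = 0.0479) or 2 (0.0246). Hoxa10 and Cd34 turned to -0.015 and -0.309 under the block. With a library left out, the log2 fold change ran from -0.28 to 0.046 for Hoxa9, -0.43 to 0.41 for Hoxa10, -0.006 to 0.47 for Meis1 and -2.17 to 1.33 for Cd34, none past the threshold.

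The 5 list calls became 0 with an estimated correlation and 0 by fry's directional form, and rose in number with an Msi2 -/- library left out. A call lost with an estimated correlation need not be lost to correlation. For late neutrophil genes the correlation was -0.007, below the preset 0.01, yet camera's unadjusted p went from 9.9e-05 to 0.0482. The other called lists had correlations above the preset, at 0.53 (MYC targets), 0.311 (G2 and M), 0.215 (p53 targets) and 0.029 (interferon). With an estimated correlation the adjusted p was 0.975 for MYC targets, 0.926 for late neutrophil genes and 0.963 for G2 and M genes. By fry it was 0.806, 0.289 and 0.457. MYC targets had 0.0559 with no filter, eosinophil, basophil and mast cell genes 0.00587 with no filter, and stem cell regulators 0.0413 at 1 CPM in 2 libraries. Fry turned the primary granule list (0.973). Lists turned without passing for dendritic genes (0.86 with no filter, 0.965 under the block), stromal genes (0.955 at 1 CPM), polycomb genes (0.92 with no filter, 0.998 under the block), oxidative phosphorylation (0.913 and 0.998) and immediate early genes (0.998 under the block).

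With a library left out the adjusted p ran from 0.00414 to 0.6 for the HOXA program, 0.0367 to 0.379 for stem cell regulators, 1.82e-05 to 0.627 for MYC targets, 0.000281 to 0.603 for primary granule genes, 2.61e-08 to 0.641 for monocyte genes, 0.00103 to 0.906 for S phase and 0.000639 to 0.391 for adhesion genes. Lists that turned in at least 1 such fit and passed in none ran from 0.627 to 0.917 (dendritic), 0.151 to 0.925 (erythroid), 0.365 to 0.953 (megakaryocyte), 0.261 to 0.917 (stromal), 0.465 to 0.906 (apoptosis), 0.431 to 0.917 (TGF-beta), 0.431 to 0.917 (Notch), 0.45 to 0.941 (polycomb), 0.599 to 0.925 (oxidative phosphorylation), 0.307 to 0.922 (glycolysis), 0.553 to 0.964 (heat shock), 0.405 to 0.906 (immediate early) and 0.0669 to 0.995 (inflammatory).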

Other observations

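Several further genes were among DESeq2's calls, while edgeR called none of them. They were chosen after their values were seen. Notch1, a receptor gene of the Notch pathway, went from 80.5 ± 5.65 CPM in the controls to 165 ± 35.8 CPM in the Msi2 -/- mice (SD, n = 2 each; log2 fold change 1.04, SE 0.172, DESeq2 adjusted p = 5.18e-06). The transcription factor genes Klf2 and Klf6 had log2 fold changes of 1.59 (SE 0.328) and 1.12 (SE 0.202), with DESeq2 adjusted p of 0.000192 and 0.000104. Mir17hg, the host transcript of a growth-promoting microRNA cluster, went from 98.3 ± 8.11 to 27.7 ± 9.54 CPM (log2 fold change -1.83, SE 0.266, DESeq2 adjusted p = 3.12e-09). Pdk1, a kinase gene that restrains pyruvate oxidation, had -0.59 (SE 0.066), and Eng, a TGF-beta co-receptor gene, -2.64 (SE 0.525). C3, a complement gene, went from 308 ± 6.12 to 699 ± 69.2 CPM (log2 fold change 1.18, SE 0.095, DESeq2 adjusted p = 2.28e-23).

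Of the stem cell regulators, Spns2, a sphingosine phosphate transporter gene, Txnip, a redox regulator gene, and Hmgb3, a chromatin protein gene, had log2 fold changes of -1.70 (SE 0.21), -0.50 (SE 0.073) and -0.59 (SE 0.125), with DESeq2 adjusted p of 1.27e-09, 6.15e-06 and 0.00406. Others of the list lay the other way: besides Cd48, DESeq2's higher calls were the transcription factor genes Fli1 (log2 fold change 0.47, SE 0.095, adjusted p = 0.00445) and Erg (0.38, SE 0.098, 0.0388). Rpl29 stood apart from the other ribosomal protein genes at 552 ± 4.79 and 337 ± 5.01 CPM (log2 fold change -0.71, SE 0.063), where 66 of the 79 genes had a log2 fold change above 0. Ribosomal protein genes have many processed copies, so how reads were assigned to Rpl29 is uncertain.

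In the 3 patterns weighed next, the tests were chosen after the result was seen, except that of T cells. The 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05: the real split gave 776 genes by DESeq2, the highest other 44, so 1 of the 3 gave as many as the real one.

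Both control libraries held Xist together with Y-linked transcripts, while the Msi2 -/- libraries held Y-linked transcripts with almost no Xist. A single exchanged label between a control and an Msi2 -/- library is argued against by Msi2 itself, which was 157 times as high in the lower control as in the higher Msi2 -/- library. A mixture of female and male cells in the control libraries may account for it: the X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape inactivation, lay 0.44 (SD 0.2 over the 4 genes) above their Msi2 -/- mean on the log2 scale in control 1 and 0.19 (SD 0.17) in control 2, which has less Xist. How cells of both sexes would come into 1 library is open, as the labels give no sex and no origin of the leukemic cells. Sex makeup and genotype differ together here, so their effects on other genes were not separated beyond leaving out X and Y genes.

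Ikzf2 stood at 86.9 CPM in the controls and 0.856 CPM in the Msi2 -/- mice, with both mice of each group close together. The share of female cells is argued against, because the excess of Ikzf2 in control 2 was 1.18 times that in control 1, where that of Xist was 0.45 times. T cells, in which Ikzf2 is also expressed and which a c-Kit sort would largely remove, are argued against by Cd3d, Cd3e and Cd3g, whose summed CPM was at most 0.06% of that of Ikzf2 in a control. A change carried with the Msi2 locus is argued against because Ikzf2 is on another chromosome; of the 40 tested genes nearest to Msi2, 10% were called by DESeq2, among them Mpo and Nog, against 5.8% of the others (Fisher's exact test, two-sided p = 0.293). As a hypothesis, loss of Msi2 may lower Ikzf2 transcripts, while a shared origin or preparation of the 2 Msi2 -/- leukemias, confounded with genotype, stays open.

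Between the 2 Msi2 -/- mice 48 genes were at least 8-fold apart, and depth is argued against because the controls, at similar depth, had 3. Dilution of Msi2 -/- replicate 1 by cells without the leukemia genes Hoxa9, Hoxa10, Meis1 and Myb is argued against by these genes. Their log2 differences between replicates 1 and 2 ran from -0.83 to 0.48 with a median of 0.05, where such dilution would need about -3. Dilution by cells that express these genes could not be tested in this way. Another cell type in one of the libraries stays open. Of the 48 genes, 12.5% (Ccr2, Cd28, Gpnmb, Mgam, Stfa1 and Thy1) were in the lists of other cell types. These lists here included the late neutrophil list and the monocyte and macrophage list, with 28 and 35 tested genes. The others held 14 (dendritic), 7 (eosinophil, basophil and mast cell), 8 (erythroid), 11 (megakaryocyte), 10 (T and NK cell), 11 (B cell) and 9 (stromal). With 13215 genes tested in all, 12.5% was well above the share of these lists among tested genes. The 12.5% lay between the bounds set for that test. Leukemias that arose from different cells could also differ in this way, which was not tested.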
